A study of Mus musculus with 12 samples.

How the data were processed

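Hepatocytes were dissociated from perfused livers of 8-week-old female Balb/c mice, and polyA-selected RNA was sequenced, per the labels' protocols. The mice had received an orthotopic injection of 4T1 cells, a mouse mammary carcinoma line that grows in Balb/c mice, or of PBS. Livers were taken at day 4 or day 21, with 3 mice in each of the 4 groups and 12 libraries in all. Each sample was assigned to its group by its own label for treatment and time. No sample was left unassigned.

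The authors deposited a single table with 1 row per gene and 1 column per library. Reads were trimmed with cutadapt, aligned with STAR 2.4.2a, counted with HTSeq and normalized with DESeq2 on GRCm38, per the submitters' processing notes. The gene annotation and the strand setting of the counting are not given in the sources used here. The values are gene counts divided by a library size factor, a normalized signal with no correction for gene length, as deposited. The authors' deposited table also states the thresholds used by the submitters, an adjusted p of 0.05, a log2 fold change of 0.58 and a maximum count of 30. Those other values were used only for a comparison of counts at day 21.

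Each library's low values were multiples of a fixed step, so whole reads could be recovered by dividing by that step. At least 99.994% of the values in each library came out within 0.1 of a whole number. Recovered totals ran from 9375095 reads (tumour day 21 replicate 8b) to 21809166 (PBS day 21 replicate 11a). No gene in the table had fewer than 6 recovered reads in its highest library. Rarer transcripts were not analysed here. The 15910 genes carried Ensembl identifiers, of which 15892 matched the GENCODE M21 annotation of GRCm38, the source of the positions given. The table repeated 10 gene symbols, and such genes were followed by identifier.

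Genes with a mean normalized count of at least 10 over the 12 libraries were tested, which left 12631. The values were taken to log2(value + 1), and limma 3.58.1 (lmFit and eBayes with trend and robust, in R 4.3.3) was fitted with 1 mean per group over all 12 libraries. Fold changes are on the log2(value + 1) scale, which understates the change of genes with few reads. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and an adjusted p under 0.05 was taken as a call. The contrasts were tumour against PBS at day 4, tumour against PBS at day 21, the difference between these tumour effects, and PBS at day 21 against PBS at day 4. Animals were the replicates, so the p-values of single genes measure the spread between mice. The camera p-values described below compare genes with genes, and at the preset correlation they reflect mainly the spread over genes. Errors given as ± are SDs over 3 mice. SE marks the standard error of a log2 fold change from limma.

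The groups, contrasts, tests, gene lists and the rule for named genes were fixed before the data were examined. The 38 lists covered hepatocyte transcription factors, urea cycle and ammonia handling, acute-phase proteins, IL-6 and STAT3 signalling, constitutive plasma proteins, lipoprotein assembly and apolipoproteins, bile acid synthesis and transport, fatty acid oxidation and ketogenesis, lipogenesis, cholesterol synthesis, gluconeogenesis and glycogen, amino acid catabolism and pyrimidine metabolism. They further covered cytochrome P450 and xenobiotic enzymes, pericentral and periportal hepatocyte genes, growth hormone and STAT5 targets, iron handling, the interferon response, chemokines and adhesion, the unfolded protein response, cell cycle and circadian clock. Lists for quality held immediate-early stress genes and mitochondrially encoded genes. Lists for other cell types held markers of Kupffer cells, neutrophils, immature myeloid cells, monocytes, T and NK cells, B and plasma cells, dendritic cells, sinusoidal endothelium, stellate cells, cholangiocytes, erythroid cells, platelets and mammary carcinoma. The 36 lists with at least 3 tested members were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast. The test was repeated with a correlation estimated for each list. Camera compares a list with all other tested genes, and fry, added later, asks whether its members move one way on balance.

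Named genes were Hnf4a and the urea cycle list at both days, whatever their values. For tumour against PBS at each day they were also the 6 genes with the largest rise and the 6 with the largest fall among called genes with a mean of at least 50 and no overlap between the groups. Predicted gene models and receptor segments were left out. For the other contrasts the first 4 each way were taken without the overlap condition. Where nothing passed, the 5 genes with the smallest unadjusted p were given as values. Up to 4 members of each list were taken in order of p in the comparison described. Reads of near-identical genes can be split or lost in counting, so values for Saa1 and Saa2, Mup, Cyp2b, Cyp2c, Cyp4a, Hba and Hbb, Orm, and Hamp and Hamp2 are uncertain. Where PBS libraries held no reads of a gene, the fold is given as a lower bound against a floor of 3 reads over the group. With 1 to 3 reads it is a ratio of reads per library depth with an exact 95% counting interval. Such intervals and floors cover counting error only.

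The fitting code was tested on data simulated from the real means and depths with 200 genes changed. In the day 4 comparison, 40.4% of 2-fold and 84.7% of 4-fold changes were recovered among 12564 genes. In the day 21 comparison these were 37.8% and 86.7% among 12557 genes. The difference between the tumour effects gave 9.09% and 59.6% among 12572 genes, and the PBS comparison over time 42.4% and 83.8% among 12578 genes. Of 200 random lists of 20 genes in the simulated day 21 comparison, 6 had a camera p under 0.05. Genes were simulated independently of each other, so this count does not cover lists whose members move together.

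The analysis was repeated with pseudocounts of 0.5 and 5, no filter and a mean of at least 50, TMM, equal-total and quantile scaling, only the groups compared, no robust step, limma's array weights, the letter b in some day 21 sample names as a covariate, a log2 fold change of at least 1, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. A covariate made from the endothelial markers, a fit without both libraries richest in myeloid transcripts, and fry were added after seeing the data. The meaning of the letters a and b in sample names was not stated, and they were not used as groups. The T and NK cell list, with 1 tested member, and the mammary carcinoma list, with 0, were too small for a set test.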

Results

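RNA of hepatocytes from 12 female Balb/c mice was measured as normalized read counts, 3 mice in each of 4 groups. The groups were mice injected with 4T1 mammary carcinoma cells or with PBS and taken at day 4 or day 21. Recovered depth ranged from 13421218 to 19634259 reads at day 4 and from 9375095 to 21809166 at day 21. Albumin took 7.82% to 13.9% of the reads of a library and mitochondrially encoded genes 4.93% to 10.4%. Tumour day 21 replicate 7 stood apart, with a median Pearson correlation of 0.83 to the other libraries. Tumour day 21 replicates 8b and 9a had 0.926 and 0.937, and the other libraries 0.961 to 0.973. The leading principal component held 60.8% of the variance. It placed replicates 7, 8b and 9a at 136, 60.7 and 65.4 and every other library at -7.43 or below.

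The title of the series asks about inflammation, loss of HNF4a and metabolism in the liver of mice with a tumour elsewhere. Hnf4a, which encodes a nuclear receptor that maintains hepatocyte gene expression (ENSMUSG00000017950, GRCm38 chromosome 2, 163506808 to 163572910, plus strand), had mean normalized counts of 10150 ± 919.1 in PBS and 12000 ± 1365 in tumour mice at day 4. At day 21 the means were 9923 ± 1058 and 10190 ± 1638. The log2 fold change was 0.24 at day 4 (95% interval -0.14 to 0.62; limma adjusted p = 0.876) and 0.03 at day 21 (-0.35 to 0.41; adjusted p = 0.937). The day 21 value turned to -0.03, -0.05 and -0.06 without tumour day 21 replicates 8b or 9a or PBS day 21 replicate 11a. The intervals leave out a fall of 1 on the log2 scale at both days, and protein was not measured.

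The urea cycle list holds enzymes and transporters of ammonia, urea and related amino acids, not all acting in 1 direction. Of its 13 members, 0 passed in limma at day 4 or day 21, over all genes or adjusted over the list alone. At day 21 Otc, ornithine transcarbamylase, had a log2 fold change of -0.71 (-1.16 to -0.25; limma adjusted p = 0.0586). Cps1, which makes carbamoyl phosphate, had -0.28 (adjusted p = 0.647) and Ass1, argininosuccinate synthase, -0.50 (adjusted p = 0.224). Arg1, Asl, Slc25a15, Glud1 and Glul had 0.35, 0.19, 0.10, 0.14 and 0.71, and Nags, Slc25a13, Gls2, Slc25a22 and Aqp9 had -0.26, -0.49, -0.52, -0.29 and -0.38. At day 4 Cps1, Otc, Arg1 and Nags had 0.17, 0.12, 0.33 and 0.38. The list median was 0.12 at day 4 and -0.28 at day 21, with camera adjusted p = 0.371 and 0.133. Without tumour day 21 replicate 9a, Otc was called lower (-0.86, limma adjusted p = 0.0294), and without 8b the list was called lower (camera adjusted p = 0.0267). Hepatocyte transcription factors had 0 of 20 members called in limma at day 21 and a median of -0.13 (camera adjusted p = 0.268). Among them Foxa1 had -0.56 (limma adjusted p = 0.0917) and Foxa3 0.59 (adjusted p = 0.11). Without PBS day 4 replicate 5, Foxa3 was called higher (adjusted p = 0.027).

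**Figure D1:**
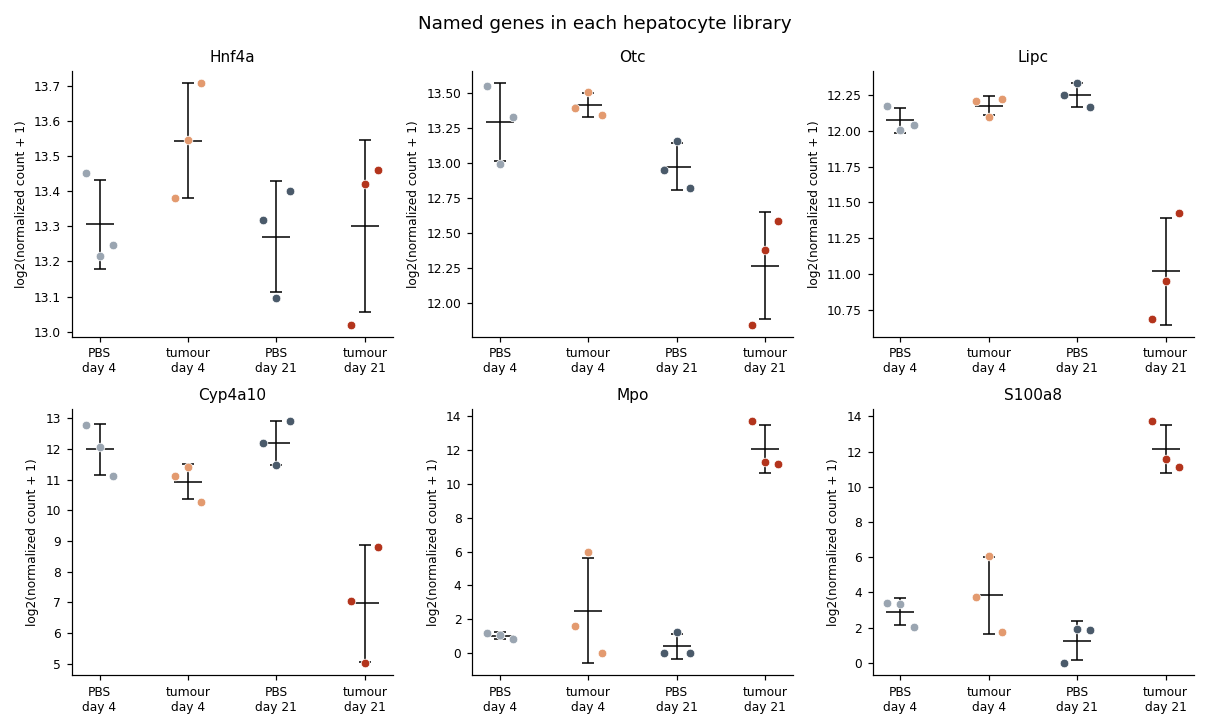
Normalized counts of 6 genes on the log2(value + 1) scale in the 12 libraries, with points for mice, a long bar for the group mean and whiskers for 1 SD; the axes do not start at 0. Hnf4a overlapped between tumour and PBS mice at day 21 (log2 fold change 0.03), while Lipc and Cyp4a10 were lower and Mpo and S100a8 higher in each of the 3 tumour mice than in each of the 3 PBS mice.

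Tumour mice at day 4 were compared with PBS mice of the same day to find early changes in hepatocytes. The acute-phase proteins, secreted by the liver in inflammation, had 26 of 31 members with a positive log2 fold change and a list median of 0.62. Lcn2, lipocalin 2, went from 338 ± 55.8 to 2180 ± 1320 normalized counts (log2 fold change 2.50, SE 0.67). Fgl1, fibrinogen-like 1, went from 8060 ± 2320 to 20800 ± 8150 (1.32, SE 0.34), and Orm3, an orosomucoid, from 99.2 ± 24 to 250 ± 62.7 (1.32, SE 0.34). None of the 31 passed over all genes in limma (adjusted p = 0.776 for these 3), while 3 passed adjusted over the list alone. The list rose against other genes (camera adjusted p = 5.78e-11), and the adjusted p = 0.942 with an estimated correlation. Library means were 12.23, 12.34 and 11.74 in tumour mice and 11.43, 11.37 and 11.61 in PBS mice (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give).

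Interferon response genes also rose as a list at day 4 (median 0.31, camera adjusted p = 5.06e-05; adjusted p = 0.942 with an estimated correlation), with 20 of 23 members positive and 0 called in limma. Igtp and Irgm1, interferon-inducible GTPases, had 0.55 and 0.49, and Isg15, a ubiquitin-like modifier, 0.72. Unfolded protein response genes rose as a list (median 0.39, camera adjusted p = 6.5e-05; adjusted p = 0.942 with an estimated correlation), with 0 of 20 called in limma. Their members included the endoplasmic reticulum chaperones Hspa5 (0.79, from 7860 ± 918 to 13900 ± 3710), Calr (0.50) and Sdf2l1 (1.06). Immature myeloid markers had a median of 1.21 (camera adjusted p = 0.0249; adjusted p = 0.942 with an estimated correlation). Fatty acid oxidation genes fell as a list (median -0.21, camera adjusted p = 0.00123; adjusted p = 0.942 with an estimated correlation), where the fuel-selection kinase Pdk4 had -2.16 (SE 0.78) and the hepatokine Fgf21 -1.07 (SE 0.47). Immediate-early stress genes (-0.59, camera adjusted p = 0.00123; Btg2 -1.13), mitochondrially encoded genes (-0.46, 0.0152; mt-Nd2 -0.62), sinusoidal endothelial markers (-0.46, 0.00484; Stab2 -0.50) and stellate markers (-0.47, 0.026; Reln -0.69) fell. The adjusted p = 0.942 with an estimated correlation held for these 4 lists too. In each list of this group 0 members passed in limma, over all genes or adjusted over the list alone. The library means of each of these lists overlapped between tumour and PBS mice of day 4 (exact two-sided permutation p = 0.2 to 0.4). Endothelial, stellate and mitochondrially encoded genes were lower in tumour mice beside the hepatocyte lists, with 16 of 16, 13 of 13 and 9 of 9 members negative.

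At the preset correlation camera called 4 lists higher and 5 lower at day 4, against 6 and 11 between PBS mice of the 2 days. Several day 4 list calls rested on single libraries. The acute-phase, interferon and unfolded protein lists kept theirs without each of the 12 libraries. Camera lost fatty acid oxidation without PBS day 4 replicate 4 (largest adjusted p = 0.194), and stress genes without tumour day 4 replicate 2 or PBS day 4 replicate 5 (0.123). Mitochondrially encoded genes were lost without tumour day 4 replicate 3, PBS day 4 replicate 4 or 5 (0.217), and immature myeloid markers without tumour day 4 replicate 2, PBS day 4 replicate 4 or 6 (0.645). Endothelial (0.18) and stellate markers (0.624) were lost without tumour day 4 replicate 3, PBS day 4 replicate 5 or 6. Tumour day 4 replicate 2 held 50 reads of Mpo, a granule enzyme of myeloid precursors, where the other 5 day 4 libraries held 0 to 2. The median, mean and camera direction differed in sign for IL-6 and STAT3 signalling (median -0.07, mean -0.17, Up), constitutive plasma proteins (0.03, -0.09, Up), pyrimidine metabolism (-0.02, -0.09, Up), chemokines (0.02, -0.08, Up) and monocyte markers (-0.09, 0.10, Up), none of them called.

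Gene by gene, limma called 0 genes higher and 0 lower at day 4 among 12631, with 761 at an unadjusted p under 0.05. EdgeR also called 0 (736 at an unadjusted p under 0.05), and DESeq2 called 1 higher and 0 lower (759). That gene was Mphosph10, a component of the U3 ribonucleoprotein that processes ribosomal RNA (DESeq2 log2 fold change 1.05, adjusted p = 0.023). In limma it went from 153.2 ± 25.63 to 315.1 ± 24.23 normalized counts (log2 fold change 1.05, SE 0.19, adjusted p = 0.776). The other genes with the smallest unadjusted p in limma were Tenm3 (-0.70), the receptor Erbb3 (-0.88), the calcineurin inhibitor Rcan1 (0.68) and the GTPase Gimap9 (1.09), all at adjusted p = 0.776. The groups did not overlap for 1108 genes (8.77%), where chance gives 10%. Without PBS day 4 replicate 6, limma called 0 higher and 3 lower.

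Tumour mice at day 21 were compared with PBS mice of the same day to find changes with an established tumour. The granule and antimicrobial genes Mpo, Ngp, S100a8, S100a9, Ltf and Elane of neutrophils and their precursors had 2 to 17 recovered reads in all over the 3 PBS libraries, and 7925 to 36714 over the 3 tumour libraries. Mpo, myeloperoxidase (ENSMUSG00000009350, GRCm38 chromosome 11, 87793581 to 87804413, plus strand), had 2 recovered reads in 3 PBS libraries and 20718 in 3 tumour libraries, a ratio of 12100 (95% counting interval 3350 to 99800). Its normalized counts were 13140.09, 2445.96 and 2273.92 in replicates 7, 8b and 9a. Ngp, neutrophilic granule protein, rose from 1.573 ± 1.387 to 10170 ± 11130 (log2 fold change 11.58, SE 0.95, limma adjusted p = 0.000313). The calprotectin subunits S100a8 and S100a9 rose by 10.87 and 10.52 (limma adjusted p = 0.000325 and 0.000545) and the iron-binding lactoferrin gene Ltf by 10.35 (0.000378). Elane, neutrophil elastase, had 2 PBS reads and 7925 tumour reads (ratio 4620, 1280 to 38200).

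The neutrophil list had 14 of 15 members called higher and 0 lower in limma (14 adjusted over the list alone). Its median was 6.88, or 6.89 with members absent from PBS at their lower bound (camera adjusted p = 1.15e-20; adjusted p = 0.124 with an estimated correlation). Camp, the cathelicidin precursor, had 2 PBS reads and a ratio of 2570 (712 to 21300). Immature myeloid markers had 8 of 8 called higher (8 adjusted over the list alone), with a median of 9.18, or 9.63 with bounds (camera adjusted p = 1.4e-15; adjusted p = 0.124 with an estimated correlation). Of the tested members, 2 neutrophil and 0 immature myeloid genes had a PBS mean of at least 10. The others passed the filter only through the tumour libraries, so the share called higher is partly set by the filter. It left in 15 of 16 neutrophil and 8 of 8 immature myeloid genes. Ms4a3, a granulocyte and monocyte progenitor gene, had 0 PBS reads and was at least 907-fold higher. The chitinase-like Chil3 was at least 362-fold and the granulocyte factor Cebpe at least 300-fold higher. Cathepsin G, Ctsg, had 1 PBS read and a ratio of 6020 (1080 to 238000). Sinusoidal endothelial markers had 0 of 16 called in the same libraries (median 0.33, camera adjusted p = 0.383), or 1 higher without tumour day 21 replicate 8b, the scavenger receptor gene Lyve1 (1.78, limma adjusted p = 0.0274).

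Monocyte markers rose with them, 6 of 9 called higher in limma and 7 adjusted over the list alone (median 3.76, camera adjusted p = 1.82e-07; adjusted p = 0.235 with an estimated correlation). Spn, leukosialin, rose by 6.34, the integrin gene Itgam by 4.96 and the chemokine receptor gene Ccr2 by 4.60 (limma adjusted p = 0.00131, 0.00176 and 0.00867). Ly6c2 had 1 PBS read and a ratio of 362 (64.5 to 14300). Kupffer cell and macrophage markers had 2 of 16 called, over all genes and adjusted over the list alone (median 1.27, camera adjusted p = 0.000262; adjusted p = 0.48 with an estimated correlation). Marco, a scavenger receptor gene, rose by 3.40 (limma adjusted p = 0.00801) in all leave-outs, and the perforin-like Mpeg1 by 1.01 (adjusted p = 0.0425). The Mpeg1 call was lost without tumour day 21 replicates 7, 8b or 9a, PBS day 21 replicates 10a, 11a or 12b, tumour day 4 replicate 3 or PBS day 4 replicate 4 (largest adjusted p = 0.194), which left 1 of the 2 except without 8b. Platelet markers had 3 of 4 called (4 adjusted over the list alone; median 1.92, camera adjusted p = 0.00126; adjusted p = 0.235 with an estimated correlation), led by the platelet chemokine Ppbp (4.79, limma adjusted p = 0.00896). That count was 0 of 3 without replicate 7 and 1 without PBS day 21 replicates 10a or 12b. Of 12 monocyte and 8 platelet genes in the table, 9 and 4 passed the filter, and 4 and 3 of these had a PBS mean of at least 10. Both counts therefore leave out members with a low mean over the 12 libraries.

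Genes of other lineages were compared at day 21 as well. B and plasma cell markers had 0 of 4 called over all genes in limma and 3 adjusted over the list alone (median 2.46, camera adjusted p = 0.0107; adjusted p = 0.328 with an estimated correlation). Without tumour day 4 replicate 2 or 3, 1 was called. Dendritic cell markers had 0 of 6 (1.04, camera adjusted p = 0.132). Stellate markers had 2 of 13, and 2 adjusted over the list alone (0.65, camera adjusted p = 0.0307; adjusted p = 0.652 with an estimated correlation), with the collagen gene Col1a1 at 3.05 (limma adjusted p = 0.0281). The camera call was lost without replicate 7 or PBS day 21 replicate 12b (largest adjusted p = 0.626). The gene count was 0 without replicate 7, PBS day 21 replicates 10a or 12b, and 1 without tumour day 21 replicate 9a, PBS day 21 replicate 11a, tumour day 4 replicate 1 or PBS day 4 replicate 5. Cholangiocyte markers had 1 of 6 (0.62, camera adjusted p = 0.354), the osteopontin gene Spp1 (2.43, limma adjusted p = 0.0445), lost without each of the 6 day 21 libraries or PBS day 4 replicate 4. Erythroid markers had 0 of 5 over all genes and 3 adjusted over the list alone (3.61, camera adjusted p = 0.144), with the haemoglobin genes Hba-a1, Hbb-bs and Hba-a2 at 3.63, 3.79 and 3.61 (limma adjusted p = 0.0888, 0.0904 and 0.124). Without tumour day 4 replicate 2 or 3, 2 erythroid genes were called. Of the T and NK cell list, 12 of 18 members were in the table and only Nkg7, a cytotoxic granule gene, was tested. It had 2 PBS reads and 568 tumour reads, a ratio of 331 (91.3 to 2740), with limma adjusted p = 0.00093. The other members in the table had a mean under 10 over the 12 libraries, so Nkg7 does not stand for the list. The mammary carcinoma list had 1 of 13 members in the table and 0 tested, so 4T1 transcripts were not examined through it.

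**Figure D2:**
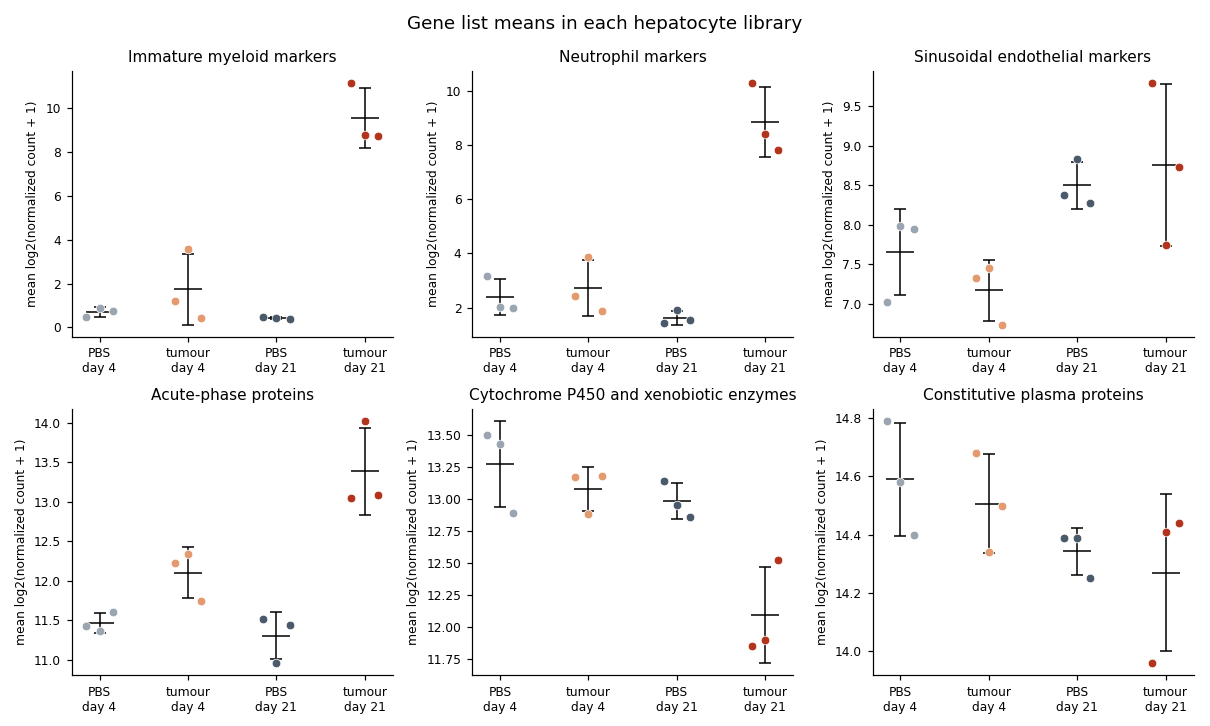
Mean log2(normalized count + 1) of the members of 6 gene lists in the 12 libraries, with points for mice, a long bar for the group mean and whiskers for 1 SD; the axes differ and do not start at 0. Immature myeloid markers averaged 11.13, 8.78 and 8.71 in the tumour mice at day 21 against 0.47, 0.41 and 0.40 in PBS mice, while constitutive plasma proteins overlapped between those groups.

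Acute-phase genes were the broadest rise among hepatocyte lists at day 21, with 27 of 31 members called higher and 1 lower in limma, and 29 and 1 adjusted over the list alone. The median was 1.74 (camera adjusted p = 4.12e-21; adjusted p = 0.208 with an estimated correlation). Lcn2 rose from 280 ± 183 to 15500 ± 8640 normalized counts (log2 fold change 6, SE 0.67, limma adjusted p = 0.000832). Neutrophil markers rose in the same libraries (list median 6.88), so the cell of origin of the Lcn2 transcripts was not settled. Lrg1, a leucine-rich glycoprotein, rose from 3550 ± 842 to 21600 ± 8000 (2.57, SE 0.31, adjusted p = 0.00073). The metal-binding Mt2 rose by 4.16 and Orm3 by 3.01 (limma adjusted p = 0.000705 and 0.000553). The lower member was Hamp, the iron hormone hepcidin (-1.26, limma adjusted p = 0.0371), called neither without tumour day 21 replicates 7 or 9a nor without PBS day 21 replicates 10a, 11a or 12b. The higher count was 17 without PBS day 21 replicate 12b. Replicate 7, richest in myeloid transcripts, did not have the highest acute-phase mean (13.05, against 14.02 and 13.09 in 8b and 9a).

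IL-6 and STAT3 signalling genes moved the same way, 6 of 18 higher and 0 lower in limma (6 and 1 adjusted over the list alone; median 0.78, camera adjusted p = 0.000262; adjusted p = 0.208 with an estimated correlation). Stat3, the transcription factor downstream of IL-6, rose from 1600 ± 164 to 3760 ± 404 (1.23, SE 0.14, limma adjusted p = 0.000569). The receptor subunit gene Il6st rose by 0.95 and the nuclear inhibitor gene Nfkbiz by 1.20 (adjusted p = 0.00866 and 0.00747). The count was 3 without replicate 7 or PBS day 21 replicate 12b, and 1 was lower without tumour day 21 replicate 9a. Chemokine and adhesion genes had 3 of 14 higher in limma, and 7 higher and 2 lower adjusted over the list alone (median 1.40, camera adjusted p = 0.013; adjusted p = 0.397 with an estimated correlation). Icam1, which binds leukocyte integrins, rose by 1.37 (limma adjusted p = 0.0118; 0.0565 without replicate 7). The count was 0 without replicate 7, 1 without PBS day 21 replicate 12b and 6 without tumour day 4 replicate 3, and 2 were lower without 9a.

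Interferon response genes had 2 of 23 higher, and 2 adjusted over the list alone (median 0.32, camera adjusted p = 0.00684; adjusted p = 0.519 with an estimated correlation). These were the immunoproteasome gene Psmb8 (0.58) and the peptide transporter gene Tap1 (0.67) at limma adjusted p = 0.0418 and 0.0426. Neither passed without tumour day 21 replicates 7, 8b or 9a or PBS day 21 replicates 11a or 12b, and 1 passed without PBS day 21 replicate 10a, tumour day 4 replicate 2 or PBS day 4 replicate 5. The camera call was lost without PBS day 21 replicate 12b (0.0848). Unfolded protein response genes had 2 higher and 1 lower of 20, or 3 and 1 adjusted over the list alone (median 0.30, camera adjusted p = 0.029; adjusted p = 0.48 with an estimated correlation). Chac1, which degrades glutathione, rose by 2.29 while the pseudokinase gene Trib3 fell by 2.32 (limma adjusted p = 0.00448 and 0.00122). The camera call was lost without tumour day 21 replicates 7 or 8b or PBS day 21 replicate 11a (0.166), and 1 was higher without replicate 7 or PBS day 21 replicate 12b. Cell cycle genes had 17 of 25 higher in limma and 23 adjusted over the list alone (median 2.97, camera adjusted p = 2.83e-15; adjusted p = 0.235 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, rose by 4.26, the mitotic kinase Aurka by 2.23 and the replication helicase gene Mcm4 by 1.82 (limma adjusted p = 0.0015, 0.00801 and 0.00845). The count was 6 of 23 without replicate 7, and 11, 7 and 6 without PBS day 21 replicates 10a, 11a and 12b. Cell cycle means were 8.40, 6.70 and 7.08 in replicates 7, 8b and 9a, where immature myeloid means were 11.13, 8.78 and 8.71.

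Genes called lower at day 21 included metabolic genes of the hepatocyte. The 6 largest falls under the naming rule were Krt23, a keratin gene, from 117.1 ± 53.34 to 2.05 ± 2.878 (log2 fold change -5.62, SE 0.60, limma adjusted p = 0.000394), the fatty acid hydroxylase genes Cyp4a10 and Cyp4a14 (-5.23 and -4.47, 0.00416 and 0.0122), the thioesterase gene Acot1 (-3.68, 0.0243), Cyp2a22 (-3.52, 0.00468) and the lipoprotein receptor gene Vldlr (-3.35, 0.00626). Krt23 lies at GRCm38 chromosome 11, 99477974 to 99493137 (minus strand), and Cyp4a10 at chromosome 4, 115518264 to 115533649 (plus strand). Cyp4a14 was lost without tumour replicate 7 or PBS replicate 12b (largest adjusted p = 0.0609), and Acot1 without tumour replicates 7 or 8b or PBS replicates 10a or 12b (0.0994).

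Cytochrome P450 and xenobiotic enzymes had 11 of 28 lower and 0 higher in limma, with 15 lower and 1 higher adjusted over the list alone (median -1.02, camera adjusted p = 7.75e-11; adjusted p = 0.235 with an estimated correlation). Cyp2c50 went from 10900 ± 1440 to 4420 ± 712 (-1.31, SE 0.19, limma adjusted p = 0.00193), and Cyp2c37, Cyp2b9 and Cyp2c29 fell by 1.87, 1.45 and 1.48 (adjusted p = 0.00203, 0.00417 and 0.0042). The count was 5 without replicate 7, 7 without 8b or PBS day 21 replicate 11a, and 6 without PBS day 21 replicates 10a or 12b, and 1 was higher without PBS day 4 replicates 4 or 6. Fatty acid oxidation and ketogenesis had 8 of 30 lower, and 21 lower and 1 higher adjusted over the list alone (median -0.55, camera adjusted p = 7.75e-11; adjusted p = 0.235 with an estimated correlation). Ehhadh, a peroxisomal oxidation enzyme, fell by 1.47 (limma adjusted p = 0.0136), a call lost without tumour replicate 7 or PBS replicates 11a or 12b (0.0694). The count was 1 without replicate 7 or PBS day 21 replicate 12b, 4 without 10a or 11a, 5 without 8b and 16 without 9a. Among these lists replicate 7 alone also had the highest endothelial mean of day 21, 9.79 against 7.74 and 8.73 in the other tumour libraries and 8.28 to 8.83 in PBS.

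Amino acid catabolism had 5 of 39 lower in limma and 11 adjusted over the list alone (median -0.55, camera adjusted p = 1.42e-09; adjusted p = 0.328 with an estimated correlation). Agxt, which detoxifies glyoxylate, went from 6440 ± 1550 to 2800 ± 658 (-1.20, SE 0.22, limma adjusted p = 0.00751). The count was 1 without tumour replicate 7 or PBS replicates 11a or 12b, 3 without 10a and 9 without 9a. Bile acid synthesis and transport had 1 of 18 lower and 8 adjusted over the list alone (median -0.66, camera adjusted p = 1.31e-06; adjusted p = 0.235 with an estimated correlation). The 1 was the organic anion transporter Slco1a4 (-1.05, limma adjusted p = 0.0153), lost without tumour replicate 7 or PBS replicate 10a (0.08). The count was 0 in those cases, 2 without tumour day 4 replicate 1, 3 without 9a and 5 without 11a. Lipogenesis had 4 of 19 lower, and 4 adjusted over the list alone (median -0.43, camera adjusted p = 0.00179; adjusted p = 0.48 with an estimated correlation), led by the carbohydrate-response factor Mlxipl (-1.07, limma adjusted p = 0.0201). The count was 0 without tumour replicate 7 or PBS replicates 11a or 12b and 1 without 8b.

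Growth hormone and STAT5 targets had 3 of 19 lower in limma and 4 adjusted over the list alone (median -0.40, camera adjusted p = 0.00226; adjusted p = 0.328 with an estimated correlation). Cyp2b13 fell by 2.10 (limma adjusted p = 0.00201), and the count was 1 without tumour replicate 7 or PBS replicate 12b and 6 without 9a. Pericentral genes had 2 of 16 lower, and 2 adjusted over the list alone (median -0.54, camera adjusted p = 0.00793, 0.052 without PBS replicate 10a; adjusted p = 0.48 with an estimated correlation). These were Cyp2c37 and the aryl-hydrocarbon-inducible Cyp1a2, which fell by 1.40 (limma adjusted p = 0.00786). Both also belong to the cytochrome P450 list, and 5 of the 16 pericentral genes are held by another list, so this is not a separate finding. Gluconeogenesis and glycogen genes had 1 of 17 lower, with 1 higher and 3 lower adjusted over the list alone (median -0.32, camera adjusted p = 0.0229, 0.132 without replicate 7; adjusted p = 0.48 with an estimated correlation). Ugp2, which makes UDP-glucose, fell by 0.99 (limma adjusted p = 0.00362). The lower count was 2 without 9a and 3 without 10a, and 1 was higher without 9a or PBS day 4 replicate 6. Lipoprotein genes had 1 of 15 lower and 2 adjusted over the list alone (median -0.30, camera adjusted p = 0.0229; adjusted p = 0.48 with an estimated correlation). The hepatic lipase gene Lipc went from 4865 ± 284.7 to 2125 ± 561.8 (-1.23, SE 0.17, limma adjusted p = 0.00167). The camera call was lost without tumour replicate 7 or PBS replicate 10a (0.196), the lower count was 2 without 9a, and 1 was higher without 8b.

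The remaining lists were not called at day 21. Constitutive plasma proteins, such as albumin and clotting factors, had 1 of 26 lower and, adjusted over the list alone, 1 higher and 2 lower (median -0.01, camera adjusted p = 0.517). Under equal totals and quantile scaling that median was 0.01 and 0.03. Klkb1, plasma prekallikrein, was the called member (-0.70, limma adjusted p = 0.0357), lost without tumour replicate 7 or PBS replicates 10a, 11a or 12b (0.169), while 3 were lower without 9a and 1 higher without PBS day 4 replicate 4. Periportal genes had 1 of 16 lower and 2 adjusted over the list alone (-0.36, camera adjusted p = 0.15), cholesterol synthesis 1 of 20 higher and 0 adjusted over the list alone (0.23, 0.383), and iron handling 1 higher and 2 lower of 17, with 1 and 3 adjusted over the list alone (-0.24, 0.369). Pyrimidine metabolism had 1 higher and 1 lower of 16, with 2 and 1 adjusted over the list alone (median -0.08, mean 0.02, camera direction Down, 0.677). Stress genes had 2 higher and 3 lower of 20, with 4 and 5 adjusted over the list alone (-0.41, 0.31). The circadian clock had 0 of 17 (-0.07, or 0.02 under quantile scaling, 0.677) and mitochondrially encoded genes 0 of 9 (-0.02, or 0.01 under equal totals, 0.829).

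Called members of these last lists were the periportal P450 gene Cyp2f2 (-1.66, limma adjusted p = 0.036), the squalene epoxidase gene Sqle (1.16, 0.0468), the zinc and iron transporter gene Slc39a14 (0.87, 0.0272), Hamp2 (-2.27, 0.043), the thymidine phosphorylase gene Tymp (-1.60, 0.0274) and the CTP synthase gene Ctps (1.09, 0.0382). Among stress genes Ier3 (2.11, 0.0184) and the heat shock gene Hspa1a (3.00, 0.0381) were higher and the transcription factors Atf3 (-2.34, 0.0387) and Nr4a1 (-3.17, 0.0425) and the phosphatase gene Dusp1 (-1, 0.0409) lower. Nr4a1, outside the first 4 stress genes by p, was named after its value was seen. Cyp2f2 also belongs to the cytochrome P450 list. Most of the calls in these lists rested on single libraries, given here as day 21 libraries unless stated. Periportal calls fell to 0 without 8b, 10a, 11a, 12b or tumour day 4 replicate 1, and became 1 higher and 0 lower without 7. They were 1 and 1 without tumour day 4 replicate 3, 2 lower without PBS day 4 replicates 4 or 5 and 3 lower without 9a. Cholesterol calls fell to 0 without 8b, 10a, 11a, 12b, tumour day 4 replicate 3 or PBS day 4 replicates 4, 5 or 6, and became 1 lower without 9a. Iron handling had 0 higher without 8b, 10a, 11a or 12b. Its lower calls were 0 without 7, 11a or 12b and 1 without 8b, 9a, 10a, tumour day 4 replicate 1 or PBS day 4 replicates 4, 5 or 6. Pyrimidine calls fell to 0 either way without 7, 11a or 12b, with 0 higher without 10a and 2 lower without 9a. Stress calls fell to 0 either way without 7, 11a or 12b, with 1 higher without 10a, 0 lower without 9a and 1 lower without 8b, tumour day 4 replicate 2 or PBS day 4 replicate 5.

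**Figure D3:**
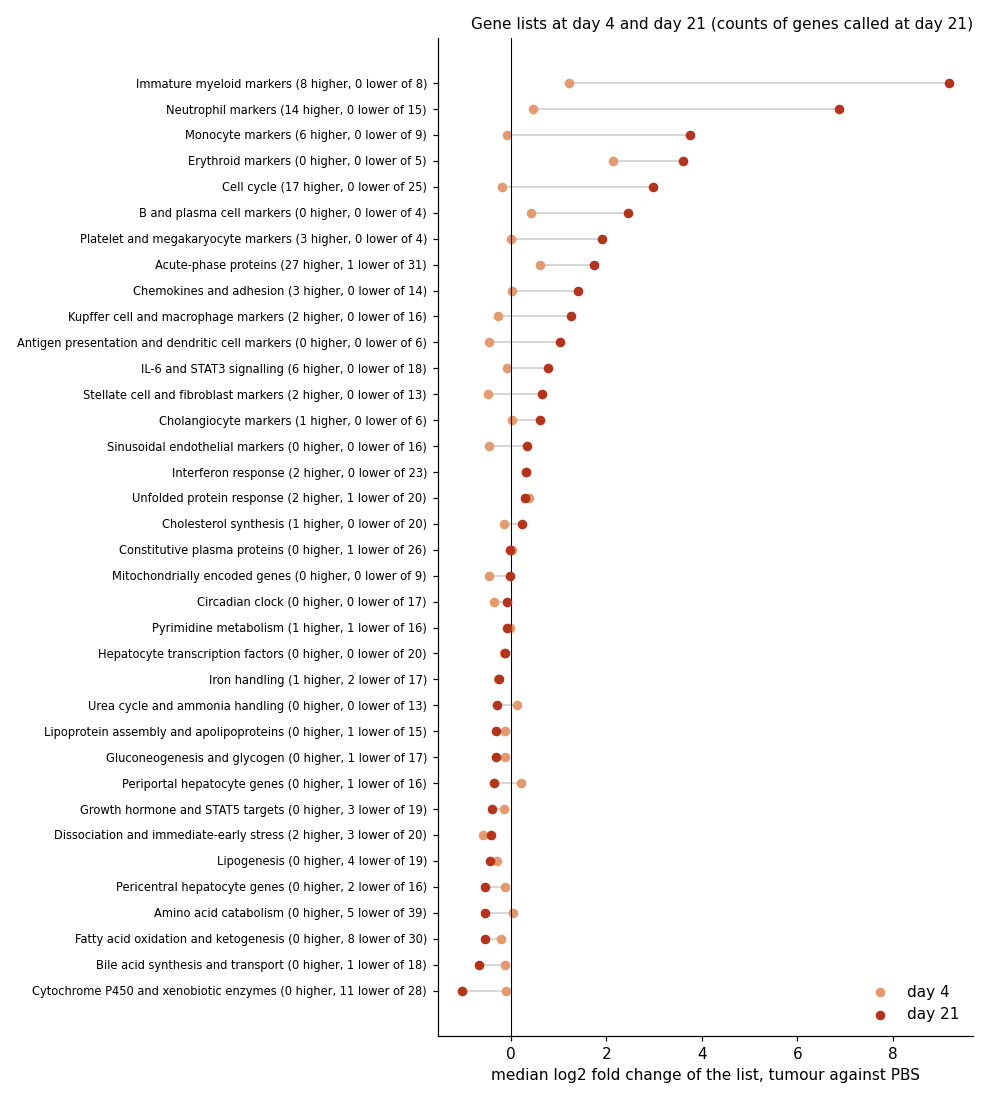
Median log2 fold change (horizontal axis, tumour against PBS on the log2(value + 1) scale) of the 36 tested lists at day 4 (light points) and day 21 (dark points), joined by a line, with the number of members called at day 21 beside each name. Immature myeloid markers reached 9.18 at day 21, and cytochrome P450 and xenobiotic enzymes had the lowest median of these lists, -1.02.

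In all, limma called 684 genes higher and 308 lower at day 21 among 12631, of which 607 and 144 changed by at least 1 on the log2 scale. EdgeR called 887 and 286, with 682 and 275 shared, and DESeq2 1195 and 583, with 672 and 306 shared. At the thresholds deposited by the authors limma called 676 higher and 276 lower, edgeR 878 and 251 and DESeq2 1146 and 425. Groups did not overlap for 4114 genes (32.6%, where chance gives 10%). Higher genes made up 69.0% of the calls, or 54.9% (700 higher, 574 lower) under quantile scaling, which moved the median fold change of all genes from 0.02 to -0.11. The share was 58.9% (344 and 240) with a mean of at least 50. Without replicate 7 the counts were 256 and 70, of which 253 and 70 were also called with it. Without both replicate 7 and tumour day 4 replicate 2 they were 304 and 66. They were 439 and 169 without PBS day 21 replicate 10a, 379 and 113 without 11a, 307 and 70 without 12b, 707 and 186 without 8b, and 710 and 461 without 9a.

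The difference between the tumour effects at day 21 and day 4 was tested directly. Granulocyte genes had a larger effect at day 21. Ngp differed by 11.50 (SE 1.34, limma adjusted p = 0.02), S100a8 by 9.93, Ltf by 9.88 (both 0.0274) and Mpo by 10.14 (0.0321). Hepatic lipase Lipc differed by -1.33 (limma adjusted p = 0.0387), retinol saturase Retsat by -2.12 and the glutathione transferase gene Gstt3 by -2.11 (both 0.0456). Immature myeloid markers had 8 of 8 members called and neutrophil markers 9 of 15 in limma, or 8 and 14 adjusted over the list alone. Mt2 (4.21, limma adjusted p = 0.0274), Chac1 (3.25, 0.0274) and Rrm2 (4.15, 0.0488) were the called members of the acute-phase, unfolded protein and cell cycle lists, of which 13, 1 and 20 passed adjusted over the list alone. For Mt2 most of the difference lay in PBS mice, with means of 1728 at day 4 and 218.6 at day 21 against 1728 and 4030 in tumour mice. Limma called 81 genes with a higher and 6 with a lower effect, all 81 and 6 of which were also called in the same direction at day 21.

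These calls were fragile. EdgeR called 0 higher and 0 lower (1737 at an unadjusted p under 0.05, against 1686 in limma) and DESeq2 408 and 71. Limma called 0 higher without PBS day 4 replicate 5 or PBS day 21 replicates 10a, 11a or 12b, 7 without tumour day 4 replicate 3 or PBS day 4 replicate 4, 10 without tumour day 4 replicate 1, 26 without PBS day 4 replicate 6, 27 without tumour day 21 replicate 7 and 142 without tumour day 4 replicate 2. Lower calls reached 54 without tumour day 21 replicate 9a and were 2 without PBS day 4 replicate 6, 1 without 8b, and 0 without the other libraries named except tumour day 4 replicate 2. Each of the 8 genes named by the rule was lost in 4 to 11 of the 12 leave-outs. For Ngp these were PBS day 4 replicate 5 and PBS day 21 replicates 10a, 11a and 12b (largest adjusted p = 0.0849), which also ended the other 7 calls (0.0936 to 0.14).

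Camera called 11 lists with a larger and 6 with a lower effect at day 21, among them acute-phase proteins (median difference 1.04, adjusted p = 5.57e-11; adjusted p = 0.347 with an estimated correlation) and amino acid catabolism (-0.62, adjusted p = 6.64e-11; adjusted p = 0.364 with an estimated correlation). Of these calls, endothelial markers were lost in 5 of the 12 leave-outs, periportal genes in 4, growth hormone targets in 3, chemokines in 2 and stellate markers in 1, and the urea cycle list, not called with all libraries, was called in 6. Hnf4a differed by -0.21 (95% interval -0.74 to 0.33; limma adjusted p = 0.768) and Otc by -0.83 (-1.47 to -0.19; 0.23). Across the 12631 genes, which are not independent replicates, fold changes at the 2 days had a Pearson correlation of 0.128 and a Spearman correlation of 0.122, and 55.3% had the same sign. No library was shared between them. Over the 992 genes changed at day 21 the correlations were 0.349 and 0.262. Of 20 labellings of the day 4 libraries, 7 gave a Pearson correlation as high over all genes and 6 over the changed genes (one-sided exact permutation p = 0.35 and 0.30). The correlation over all genes had a jackknife SE of 0.349 over libraries and ranged from -0.133 without tumour day 4 replicate 2 to 0.35 without replicate 3.

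PBS mice of day 21 were compared with PBS mice of day 4 as the background of age, day and handling. Metallothionein Mt2 went from 1728 ± 874.5 to 218.6 ± 68.15 (log2 fold change -2.91, limma adjusted p = 0.694). The other genes with the smallest unadjusted p were Fam46c (-1.57), the kinase gene Nuak2 (1.43), the phospholipase gene Plce1 (-0.83) and the Wnt receptor gene Fzd7 (1.14), all at limma adjusted p = 0.938. Limma called 0 genes either way (504 at an unadjusted p under 0.05), edgeR 0 (463) and DESeq2 0 higher and 5 lower (589). The 5 were Mt2 (-2.98, DESeq2 adjusted p = 6.06e-07), Tcim (-2.25, 0.00163), Fam46c (-1.65, 0.00606), Spata2l (-1.50, 0.0414) and Gm33543 (-1.31, 0.0414), of which Tcim, Spata2l and Gm33543 were named after their values were seen. Without PBS day 4 replicate 6, limma called 2 higher and 13 lower. Camera called 6 lists higher and 11 lower, which became 0 and 0 with an estimated correlation (smallest adjusted p = 0.708) and 0 and 0 in fry. Endothelial markers were higher in PBS mice of day 21 (median 0.86, 16 of 16 positive, camera adjusted p = 1.48e-09; adjusted p = 0.708 with an estimated correlation), as were stellate (0.99, camera adjusted p = 4.38e-06) and Kupffer markers (0.83, 0.000614), both at an adjusted p = 0.708 with an estimated correlation. Periportal genes were lower (-0.52, 16 of 16 negative, camera adjusted p = 1.04e-06; adjusted p = 0.708 with an estimated correlation), with the serine dehydratase gene Sds at -1.06. In these 4 lists 0 members passed over all genes in limma, and 1, Sds, passed adjusted over the list alone.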

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

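The 81 and 6 genes and the 17 lists called with a different tumour effect at day 21 than at day 4, of which 0 lists were called with an estimated correlation (smallest adjusted p = 0.134), came from a planned test, and the tests of their causes were chosen after the result was seen, except the relabelling of libraries. Ngp differed by 11.50, Mpo by 10.14, S100a8 by 9.93, Ltf by 9.88, Srgap3 by -2.60, Retsat by -2.12, Gstt3 by -2.11 and Lipc by -1.33. Of 100 labellings drawn from the 200 possible within each day, 6 gave as many calls as the real 87, with a highest other count of 428, so chance cannot be excluded. All 6 kept the day 21 groups, as 8 of the drawn labellings did, so the count follows the day 21 grouping and says little about day 4. For day 4, day 21 and PBS over time, 10 splits each were too few to exclude chance. The real counts there were 0, 992 and 0, the highest others 1, 0 and 1, and 10, 1 and 10 of the splits reached the real count.

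Granulocyte genes were higher at day 21, and the 3 tests of this pattern were chosen after the result was seen. As lists, neutrophil markers differed from day 4 by a median of 6.26, immature myeloid markers by 7.56, monocyte markers by 4.13, platelet markers by 2.02, cell cycle genes by 3.39, Kupffer markers by 1.57, chemokines by 1.22, stellate markers by 0.95 and endothelial markers by 0.79, none called with an estimated correlation (smallest adjusted p = 0.134), and endothelial markers lost in 5 of 12 leave-outs. Replicate 7 alone is argued against, since 18 of 22 called granulocyte genes were still called without it. An equal rise of every non-parenchymal cell type is argued against too, since the granulocyte rise exceeded the endothelial rise by at least 6.68 in each tumour library. Endothelial markers changed by 1.29, -0.76 and 0.24 and Kupffer markers by 2.69, 0 and 1.47 in replicates 7, 8b and 9a. A smaller rise of several cell types therefore stays open for 7 and 9a. Blood left in the liver stays open, because the haemoglobin genes had a median log2 fold change of 3.63 and rose by 5.66, 2.56 and 2.82 in replicates 7, 8b and 9a. The values are consistent with myeloid cells, among them precursors, being carried in the preparation, and whether they sat in liver tissue or in its vessels was not tested.

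Genes called lower at day 21 were 308, metabolic and others, and the 4 tests of this pattern were chosen after the result was seen. The lists differed from day 4 by medians of -0.64 for cytochrome P450 and xenobiotic enzymes, -0.62 for amino acid catabolism, -0.52 for bile acid genes, -0.47 for fatty acid oxidation, -0.42 for periportal genes and -0.16 for growth hormone targets, none called with an estimated correlation (smallest adjusted p = 0.347), and the last 2 lost in 4 and 3 of 12 leave-outs. Replicate 7 alone is argued against for the 70 of these genes also called lower without it, and stays open for the other 238, whose median went from -0.85 to -0.73 without it at a median SE of 0.21 and 0.22. Genes called lower without 8b or 9a but not without 7 had medians of -0.66 and -0.49 in the library held out, against PBS day 4. They included 105 and 194 of the 238. Of them 98.3% and 94.7% lay below 0 there, where all genes had medians of 0.01 and 0, which goes against replicate 7 alone for these genes. The SD over genes, 0.91 and 0.47, is a spread of folds and not the error of a median. The bound was more than 1 SD in both, which 8b missed. A fall in the hepatocyte share of RNA by the median of these genes, -0.96, is argued against by the constitutive plasma proteins, with a median of -0.01 (SD 0.48 over 26 genes). The deposited scaling can absorb such a fall, but equal totals, where a lower share would show, moved that median little. A fall in the amount of RNA per cell cannot be seen under either scaling. A smaller loss stays open, since the 308 genes were chosen as lower in the same libraries. Albumin took 7.82%, 7.95% and 9.56% of reads in replicates 7, 8b and 9a, against 9.8%, 12.5% and 11.1% in PBS day 21 replicates 10a, 11a and 12b. The scaling is argued against by the 252 or more of the 308 genes still called lower under each other scaling. Food intake, body weight and the time of day of sampling were not given and stay open as other causes.

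Acute-phase genes were higher as a list at day 4, and the 3 tests of this pattern were chosen after the result was seen. At day 21 the list's tumour effect was higher than at day 4 by a median of 1.04, and that of IL-6 and STAT3 signalling by 0.91, neither called with an estimated correlation (adjusted p = 0.347 and 0.273). A single library as the source of the rise is argued against, since the list median was 0.44 to 0.77 in the 6 fits without 1 day 4 library. All 6 kept the call at the preset correlation, while with an estimated correlation there was no call to keep. A rise of stress genes as large as the acute-phase estimate of 0.63 is argued against. The stress list had a mean difference of -0.56 (95% interval -1.27 to 0.16), with its upper limit below that estimate. The acute-phase interval, -0.04 to 1.30, overlaps that of the stress list and both include 0, so a smaller part of dissociation stress stays open. Members moving together by chance stays open, with p = 0.065 for the list with an estimated correlation (adjusted p = 0.942), so an early acute-phase response may be present but is not established by 3 mice per group.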

How the results depend on the processing

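Genes called for tumour against PBS at day 21 in both the main fit and another setting kept their direction, while the numbers of calls moved. The fits share most libraries, so a kept direction could hardly fail, and genes that lost their call are not covered by it. The 684 genes called higher became 344 with a mean of at least 50, 1156 with array weights, 1195 in DESeq2 and 304 without both libraries richest in myeloid transcripts. The 308 called lower became 144 at a log2 fold change of at least 1, which follows from that rule, 574 under quantile scaling, 153 with only the groups compared, 654 with array weights, 583 in DESeq2 and 66 without both libraries. The cause of the other moves was not tested. Leaving out 1 library gave 256 to 728 higher and 70 to 461 lower. At day 4 DESeq2 called 1 gene higher against 0, and leave-outs gave 0 to 3 lower. In PBS over time DESeq2 called 5 lower against 0, and leave-outs gave 0 to 2 higher and 0 to 13 lower.

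The difference between the tumour effects moved most. Its 81 higher calls became 36 with a pseudocount of 0.5, 158 with no filter, 1 with a mean of at least 50, 50 under equal totals, 48 without the robust step, 229 with array weights, 43 with the letter b as a covariate, 0 in edgeR and 408 in DESeq2. Its 6 lower calls became 2 with a pseudocount of 0.5, 0 with a mean of at least 50, 14 under quantile scaling, 12 with array weights, 2 with the letter b as a covariate, 0 in edgeR and 71 in DESeq2. They became 1 with the endothelial covariate and 1 without both libraries richest in myeloid transcripts, alternatives chosen after seeing the data. Leave-outs gave 0 to 142 higher and 0 to 54 lower. These results may rest on few libraries, and no cause was tested.

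Lists called by camera at a preset correlation were not called with an estimated one. At day 4 the 4 higher and 5 lower lists became 0 and 0, and 0 and 0 in fry, with leave-outs giving 3 to 9 higher and 1 to 8 lower. At day 21 the 13 and 9 became 0 and 0, and 7 and 3 in fry, with leave-outs giving 11 to 14 and 7 to 11. For the difference the 11 and 6 became 0 and 0, and 3 and 0 in fry, with leave-outs giving 9 to 14 and 4 to 9. Fry was chosen after seeing the data.

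The lower end is limited. No gene in the table had fewer than 6 recovered reads in its highest library, and rarer transcripts were not analysed here. Whether depth or a filter on the deposited table set that limit was not tested. No paired analysis was possible because the groups share no replicate numbers.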

Other observations

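Gene families sharing a symbol stem, chosen after the data were seen and partly overlapping the lists, were compared at day 21. The Mup family of urinary pheromone carriers had 6 of 13 members lower in limma (median -2.45, camera adjusted p = 1.67e-07), the carboxylesterase family Ces 4 of 12 (-0.72, 1.59e-05), the glutathione transferase family Gstm 5 of 8 (-1.10, 2.04e-05) and the sulfotransferase family Sult 3 of 16 (-0.90, 2.04e-05). The whole Cyp family had 2 higher and 21 lower of 69 (-0.81, 1.2e-14). In the other direction, the protease inhibitor family Serpina had 6 of 22 higher (1.04, 0.000138), the replication helicase family Mcm 5 of 10 (1.44, 0.00729), the kinesin family Kif 9 of 27 (0.38, 0.00729) and the lectin family Clec 4 of 17 (1.23, 0.00482). The adjusted p = 0.789 with an estimated correlation held for each family except Clec (0.808). Family counts were not repeated with libraries left out. Over all tested genes, limma's 684 higher and 308 lower calls became 256 and 70 without tumour day 21 replicate 7. Immature myeloid, monocyte and Kupffer markers rose in the same tumour libraries (list medians 9.18, 3.76 and 1.27), so the cell of origin of the Mcm, Kif and Clec transcripts was not settled. Reads of close paralogs in the Mup, Cyp and Serpina families can be exchanged in counting.

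At day 4 no member of any of these families was called in limma. The proteasome family Psmd had a median of 0.27 over 14 members (camera adjusted p = 5.72e-05) and the RNA helicase family Ddx 0.17 over 33 (1e-04), both with an adjusted p = 0.642 with an estimated correlation. Collagens had -0.56 over 23 members (0.00627; adjusted p = 0.716 with an estimated correlation). In tumour day 4 replicate 2, immature myeloid markers averaged 3.55 against 1.22 and 0.45 in the other tumour mice of that day, erythroid markers 6.99 against 5.66 and 4.17, and cell cycle genes 5.97 against 4.49 and 3.83. That order of libraries was the same in the 3 lists.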
